A study of Mus musculus with 2 samples.

How the data were processed

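The measurement was DNase-seq, in which the enzyme DNase I cleaves nuclear DNA preferentially where chromatin is accessible and the ends of the released fragments are sequenced. The tissue was the adrenal gland of 10-day-old male B6CASTF1/J mice, first-generation hybrids of the C57BL/6J and CAST/EiJ strains. The labels give 1 group of 2 biological replicates and name 3 males for each. Replicate 2 carries the names of a pair of sequencing instruments in its label and replicate 1 carries none, so instrument, library and animals cannot be told apart in any difference between the replicates. With a single group, no test between conditions was possible, and all comparisons were made within and between the 2 libraries.

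Per the deposited readme text, each library had its own peak lists, footprints and per-base false discovery rates (FDR), all made from that library's own alignments to the mm10 assembly, without pooling of replicates. The programs that aligned the reads and called the sites are not given in the sources used here. The deposited signal in the peak lists is a height per peak, given by the authors' peak caller. Within each library the heights that were tested (97211 of 126988 in replicate 1 and 120460 of 141641 in replicate 2) were whole multiples of 1 smallest step (tolerance 0.05 of a step), 0.00427 and 0.00477, as a normalization per fixed number of cleavages or reads would give. The sequencing depth itself is not stated. Heights were used to rank peaks and to describe them within a library. The deposited per-base file holds FDR values of the kind of a q-value, listing bases under 0.05, and the deposited footprint file holds the constant 0.01, read here as a p-value or FDR threshold and not as a value per footprint. Each library has a shorter peak list, in which every peak holds at least 1 base with an FDR under 0.001, and a longer list with the limit at 0.05, which 4 peaks of replicate 2 did not meet. The shorter lists were used throughout, and the longer lists as an alternative. Footprints are short stretches protected from cleavage. All deposited footprints were used, of which 68.8% and 67.5% overlapped the shorter peak lists, while 58744 and 28322 lay outside the longer lists.

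Genes, exons and transcription start sites (TSS) came from the GENCODE M21 annotation, and sequence from the GRCm38.p6 assembly, which is the same build as mm10. The 21 chromosomes (19 autosomes, X and Y) were used. Positions are 1-based. Intervals overlapped when they shared at least 1 bp, with a reciprocal overlap of at least 50% as an alternative. Chance overlap was taken from 20 shuffles of the peaks within their chromosomes outside unsequenced bases, and for footprints from 20 random placements within the peaks of the longer list. A promoter was the 1000 bp on either side of an annotated TSS (500 and 2500 bp as alternatives). Peaks elsewhere were assigned in order to exons, introns and the sequence between genes, and are called distal when outside every promoter. For gene lists, counts per gene and strings at gene loci, only promoters of protein-coding genes were left out. Distal peaks there can therefore lie at promoters of other annotated genes.

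For 21911 protein-coding genes, the promoter was called accessible when a peak overlapped it. The distal density was the number of distal peaks per 10 kb in the gene body with 10 kb on each side (50 kb, or assignment to the nearest TSS, as alternatives). A set of 24 gene lists and 24 consensus strings was fixed before the data were examined. The lists covered steroid synthesis and ACTH response, adrenocortical identity regulators, zona glomerulosa, X-zone, cholesterol synthesis and uptake, chromaffin cells, the other cells of the gland, neighbouring tissues, tissues not sampled, the related cells of the testis, the circadian clock, immediate early genes and housekeeping genes. Each list was placed among 10000 random lists of the same size matched on promoter CpG content (3 bins, counted over 1001 bp) and gene length (5 bins). A list was called above other genes when it reached percentile 99 or higher in each library on its own, and below when it reached percentile 1 or lower in each. These percentiles describe the 2 libraries, since genes are not replicates. Exact (Clopper-Pearson) 95% binomial intervals were computed for promoter shares over the genes of a list and cover counting error only.

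Consensus strings were matched on both strands. In footprints, the density of matches with their centre in a footprint was divided by the density in the remaining bases of the peaks, with 0.5 added to each count, and the log2 ratio was compared with up to 50 letter shuffles of the string that kept its CpG count where possible. A string was called when it exceeded all its shuffles, or lay below all, in each library. In distal peaks, the share of 200 bp windows about the peak centre holding a match was divided by the share in windows of the same chromosome matched on GC content in bins of 2%, outside the longer lists of both libraries. A string was called when this ratio was at least 1.5 and above all shuffles in each library. The share of distal peaks holding the NR5A1 string was compared between the loci of 4 adrenal cortex lists and all other protein-coding loci, with percentiles from random matched lists, and likewise the E-box and GATA strings at chromaffin genes.

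The genes named in the text followed a rule fixed before the data were examined: 23 marker genes of the adrenal cortex and medulla, in each list the 3 members with the highest mean distal density and up to 2 members with no peak in either library, the 10 protein-coding genes with the most distal peaks in both libraries, the 5 highest shared peaks by mean rank of height, and the consensus strings with the 5 highest and 3 lowest footprint ratios. Some of the genes and strings that this rule selects are not reported here. Values are given per library or as mean ± SD over n = 2 libraries. Alternatives were the longer lists, the higher-ranked 50% of peaks by height, equal numbers of peaks, other windows, unmatched random lists, other comparison sequences for the consensus strings, and each library on its own. The restriction to peaks shared by both libraries was added after the data had been seen. The labels give 1 group, so no pairing of samples was involved.

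The distal density call and the footprint ratio were tested on simulated data. The calls for promoter shares and for strings in distal peaks were not. With the densities of the 21911 genes permuted within matching bins, 0 of 100 lists of 20 unchanged genes were called above and 1% below. Lists raised 2, 3 and 4 times were called above in 26%, 68% and 84% of 100 draws, so that a doubling of distal density would often be missed. Planted increases of 2 and 4 times in the density of a consensus in footprints were estimated as 2.07 and 4.14. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1.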

Results

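DNase I accessibility was profiled in adrenal gland tissue of 10-day-old male B6CASTF1/J mice, hybrids of the C57BL/6J and CAST/EiJ strains. The gland holds a steroid-producing cortex around a medulla of chromaffin cells, which make catecholamines. There was 1 group of 2 biological replicates, each labelled as 3 males. The deposited list of replicate 1 held 126988 peaks over 24.5 Mb and that of replicate 2 held 141641 peaks over 24.9 Mb (0.914% of the chromosomes), with median widths of 180 and 173 bp. Footprints, short stretches protected from cleavage, numbered 506257 and 324155, of which 68.8% and 67.5% overlapped these peaks, with median lengths of 10 and 9 bp. A footprint lay in 90.5% of the peaks of replicate 1 and in 63.1% of those of replicate 2. Peak heights are the authors' normalized signal, with medians of 0.965 and 0.549, and the number of reads per library is not given in the sources used here. All positions refer to mm10.

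Among the cortex markers named in advance, Nr5a1, Star, Cyp11a1, Scarb1 and Mrap had a promoter peak and distal peaks in both libraries. Nr5a1, the nuclear receptor that specifies steroidogenic cells (chromosome 2, 38692656 to 38714542), had a promoter peak at 38714441 to 38714620 with heights of 5.48 in replicate 1 and 5.31 in replicate 2, and 11 and 13 distal peaks, of which 6 were shared. Star, which moves cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), had a promoter peak starting at 25806201 with heights of 3.82 and 3.67, and 5 and 19 distal peaks, of which 4 were shared. Cyp11a1, the side-chain cleavage enzyme (chromosome 9, 58006411 to 58027023), had its highest promoter peak inside the gene at 58014901 to 58015100 in replicate 1, at an annotated internal TSS, with heights of 4.06 and 2.60, and 12 and 14 distal peaks. Scarb1, the receptor for high-density lipoprotein (chromosome 5, 125277087 to 125341094), had promoter heights of 9.46 and 8.46 and 22 and 16 distal peaks, 13 of them shared. Mrap, the accessory protein of the ACTH receptor, had promoter heights of 6.45 and 5.14.

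The promoter values of the other cortex markers ranged from no peak in either library to heights near those of Nr5a1. Mc2r, the ACTH receptor, had no promoter peak in replicate 1 and one of height 0.210 in replicate 2, beside 4 and 6 distal peaks. Hsd3b1, a steroid dehydrogenase, had no promoter peak in either library and 7 and 1 distal peaks. The promoter of Cyp11b1, which encodes the enzyme of the last step of corticosterone synthesis, carried a peak of height 1.40 in replicate 1 and none in replicate 2. For Cyp11b2, aldosterone synthase, the promoter peak was found in replicate 2 alone, with a height of 0.281. Unique mapping of reads at Hsd3b1, Cyp11b1 and Cyp11b2 was not examined, so a missing or low peak there need not mean a closed promoter. Akr1b7, an aldo-keto reductase of the cortex, had promoter heights of 2.18 and 1.30, and Akr1c18, a progesterone-converting enzyme that marks the X-zone, had 0.516 and 0.630. Gata6, a transcription factor of the cortex, had promoter heights of 5.98 and 4.63, and Wnt4, a ligand made in the outer cortex, had 5.72 and 3.83. Nr0b1, an X-linked repressor of Nr5a1 targets, had 0.768 in replicate 1 (86191641 to 86191860) and 0.959 in replicate 2 (86192721 to 86192920). These 2 peaks did not overlap. Cyp21a1, a steroid hydroxylase (chromosome 17, 34801348 to 34804561), had promoter heights of 2.13 and 1.78 and 14 and 15 distal peaks, and lies in a duplicated segment with a pseudogene copy, so its values are uncertain.

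Among chromaffin cell genes, Chga, which encodes the granule protein chromogranin A, had the highest promoter peaks of the chromaffin markers named in advance, at 4.89 and 4.04. The catecholamine enzymes Th and Dbh had 0.935 and 0.992, and 1.29 and 1.42. Pnmt, which converts noradrenaline to adrenaline, had no promoter peak in either library and 2 distal peaks in each, both shared. Hand2 had promoter heights of 1.17 and 0.997 and Gata3 had 1.14 and 1.00.

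**Figure D1:**
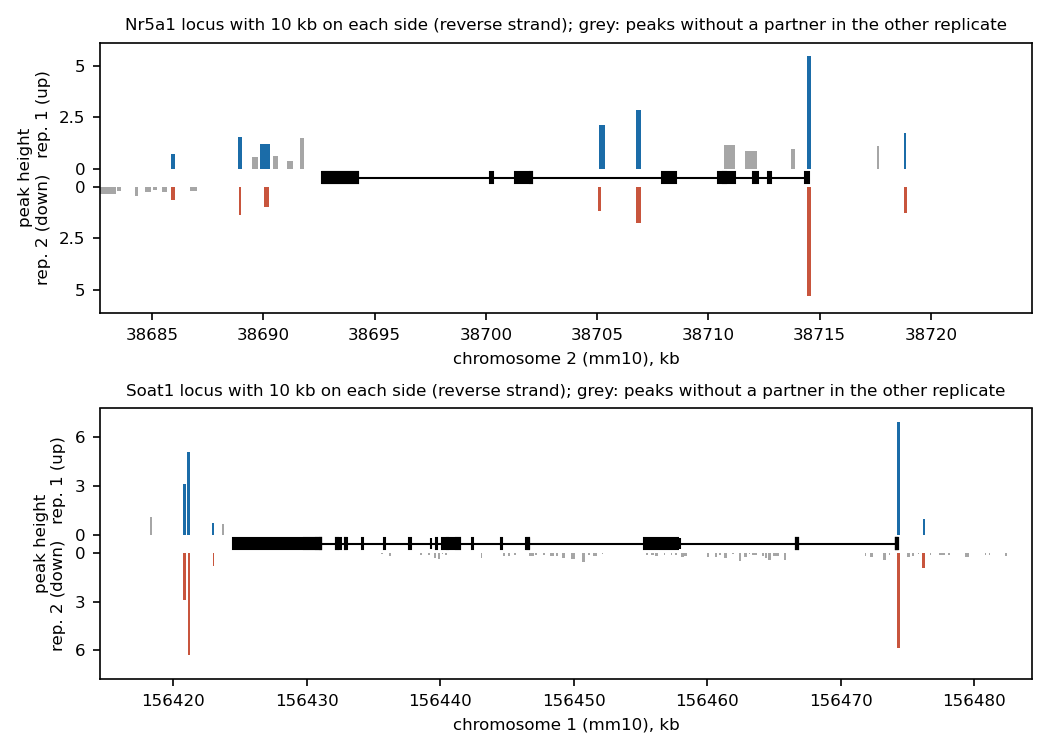
Peaks across Nr5a1 and Soat1 with 10 kb on each side, drawn to scale along mm10 in kb, with replicate 1 upward, replicate 2 downward and the bar height giving the authors' peak height. Black boxes are annotated exons, coloured bars are peaks shared by both libraries and grey bars are peaks of 1 library, which at Soat1 are mostly the low peaks of replicate 2 (58 distal peaks against 3 in replicate 1).

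Promoter accessibility of the steroid genes stood above that of matched genes. Of the 20 genes for steroid synthesis and ACTH response, 18 had a promoter peak in each library (exact 95% interval 68.3 to 98.8%), against 61.5% and 57.7% on average in random lists of the same size matched on CpG content and gene length (percentiles 99.985 and 100). Adipocyte genes were also above, with 11 and 9 of 11 promoters accessible against 58.4% and 55.9% in matched lists (percentiles 100 and 99.26). Genes of kidney tubules and podocytes were below, with 6 and 5 of 14 (percentiles 0.670 and 0.450), and so were genes of pluripotent cells, with 5 and 1 of 10 (percentiles 0.965 and 0). The other 20 of the 24 lists were not called. Compared with random lists that were not matched, none of these 4 lists was still called (ratio 1.32 for the steroid genes), with 2500 bp around a TSS the steroid list alone was still called, and with 500 bp the kidney list lost its call.

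Several lists with CpG-rich promoters were accessible throughout in both libraries. These were the 21 genes of cholesterol synthesis and uptake, the 18 of the circadian clock, the 16 immediate early genes and the 16 housekeeping genes, with every promoter accessible in each library. Adrenocortical identity regulators had 18 and 17 of 18 accessible promoters, zona glomerulosa genes 12 and 14 of 14, and the X-zone genes 4 and 3 of 5. For chromaffin cells the counts were 23 and 20 of 25, for Schwann cells and their precursors 10 and 10 of 13, for endothelial cells 18 and 13 of 19, for capsule and fibroblasts 13 and 11 of 16, and for pericytes and smooth muscle 9 and 10 of 11. Macrophage and leukocyte genes had 8 and 6 of 18 accessible promoters and erythroid genes 4 and 4 of 12. Among tissues that were not sampled, hepatocyte genes had 4 and 3 of 15, brain neuron genes 9 and 7 of 14, skeletal muscle genes 6 and 4 of 13, heart muscle genes 5 and 4 of 11 and photoreceptor genes 6 and 5 of 11. Genes of Leydig and Sertoli cells, the related cells of the testis, had 7 and 5 of 10. Across all 21911 protein-coding genes, 69.9% and 66.8% had an accessible promoter. When only peaks shared by both libraries were counted, a setting added after the data were seen, 8 lists were called, with leukocytes, brain neurons, skeletal muscle and photoreceptors added to those below.

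Called above matched genes for distal density in both libraries were the steroid, immediate early and circadian clock genes. The 20 steroid genes had 2.20 and 2.81 distal peaks per 10 kb, 3.17 ± 0.549 (SD, n = 2) times the mean of matched random lists (percentiles 100 and 99.8). Within this list the densest loci were Cyp21a1, Lipe, the hormone-sensitive lipase, with 19 and 18 distal peaks, and Soat1, which esterifies cholesterol, with 3 and 58. Immediate early genes had a ratio of 2.53 ± 0.0847 (SD, n = 2), led by Junb with 8 and 16 distal peaks, Atf3 with 13 and 65, and Fos with 3 and 20. Circadian clock genes had a ratio of 2.34 ± 0.294 (SD, n = 2), led by the transcriptional repressor Nr1d1 with 9 and 22, Per1 with 12 and 20, and Per2 with 16 and 49. The clock list was not called when each distal peak was assigned to the nearest TSS (percentiles 99.855 and 97.27). The Soat1, Atf3, Fos and Per2 counts differed several-fold between libraries, and with shared peaks alone the 3 ratios were 3.46, 2.97 and 2.39 and stayed called.

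Lists for cortical identity and for fat were high in replicate 1 and, with all peaks, passed the threshold in that library alone. Adrenocortical identity regulators had a ratio of 2.37 ± 0.820 (SD, n = 2; percentiles 100 and 95.14). Their densest loci were Hoxb9, with 19 and 23 distal peaks, Nr2f2, a nuclear receptor of the outer cortex and stroma, with 24 and 10, and Cbx2, a Polycomb protein, with 4 and 16. Adipocyte genes had 2.77 ± 1.27 (percentiles 99.99 and 89.85), with Cidec at 4 and 21, the lipid droplet coat gene Plin1 at 9 and 6 and Cebpa at 14 and 3. Zona glomerulosa genes had 1.71 ± 0.949 (percentiles 99.95 and 59.78), with the potassium channel gene Kcnk3 at 42 and 19, Wnt4 at 12 and 8 and Shh at 4 and 8. In the higher-ranked 50% of peaks, the identity regulators (percentiles 99.9 and 99.62) and the adipocyte genes (99.98 and 99.15) were called above in both libraries. With shared peaks alone, the identity regulators (ratio 2.78) and the adipocyte genes (3.13) were called above and the zona glomerulosa genes (1.89) were not.

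None of the other lists was called for distal density. Chromaffin genes had a ratio of 0.833 ± 0.509 (SD, n = 2; percentiles 80.79 and 4.09), with Gata2 at 13 and 1 distal peaks, Th at 3 and 23 and Hand2 at 6 and 2. X-zone genes had 0.471 ± 0.305, with Akr1c18, Thrb and Pik3c2g as the densest and no peak at Spink12. Cholesterol genes had 0.999 ± 0.338, with Fdps at 2 and 12, Lss at 1 and 24 and Dhcr7 at 3 and 19. Schwann cell genes had 1.46 ± 0.703 (Gfap, Ngfr and Mbp), endothelial genes 1.43 ± 0.162 (Pecam1, Sox18 and Egfl7), capsule and fibroblast genes 1.03 ± 0.493 (Gli1, Twist1 and Meox1), and pericyte and smooth muscle genes 1.35 ± 0.754 (Notch3, Cspg4 and Des). Leukocyte genes had 1.24 ± 0.332, with Cx3cr1 at 30 and 80 distal peaks over an annotated span of chromosome 9 from 119901616 to 120069879 and no peak at Tyrobp. Erythroid genes had 0.678 ± 0.209 (Klf1, Tal1 and Epor), with no peak at the near-identical globin genes Hba-a1 and Hba-a2. Kidney genes had 1.04 ± 0.157 (Slc12a3, Nphs1 and Hnf4a, with no peak at Umod), hepatocyte genes 1.48 ± 0.113 (Foxa3, Ahsg and Apoa2, with none at Fga or Serpina1a), and Leydig and Sertoli cell genes 1.45 ± 0.347 (Cyp17a1, Amh and Dhh). The ratios were 1.04 ± 0.186 for brain neurons (Dlx2, Slc17a7 and Camk2a), 0.827 ± 0.136 for skeletal muscle (Mylpf, Myog and Acta1, with none at Cav3 or Myf5) and 1.16 ± 0.0284 for heart muscle (Myl2, Tnni3 and Nppb, with none at Myl7). They were 0.634 ± 0.278 for photoreceptors (Sag, Nr2e3 and Prph2), 0.603 ± 0.246 for pluripotent cells (Utf1, Tfcp2l1 and Nanog, with none at Zfp42) and 0.948 ± 0.185 for housekeeping genes (Gapdh, Eef2 and Actb).

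**Figure D2:**
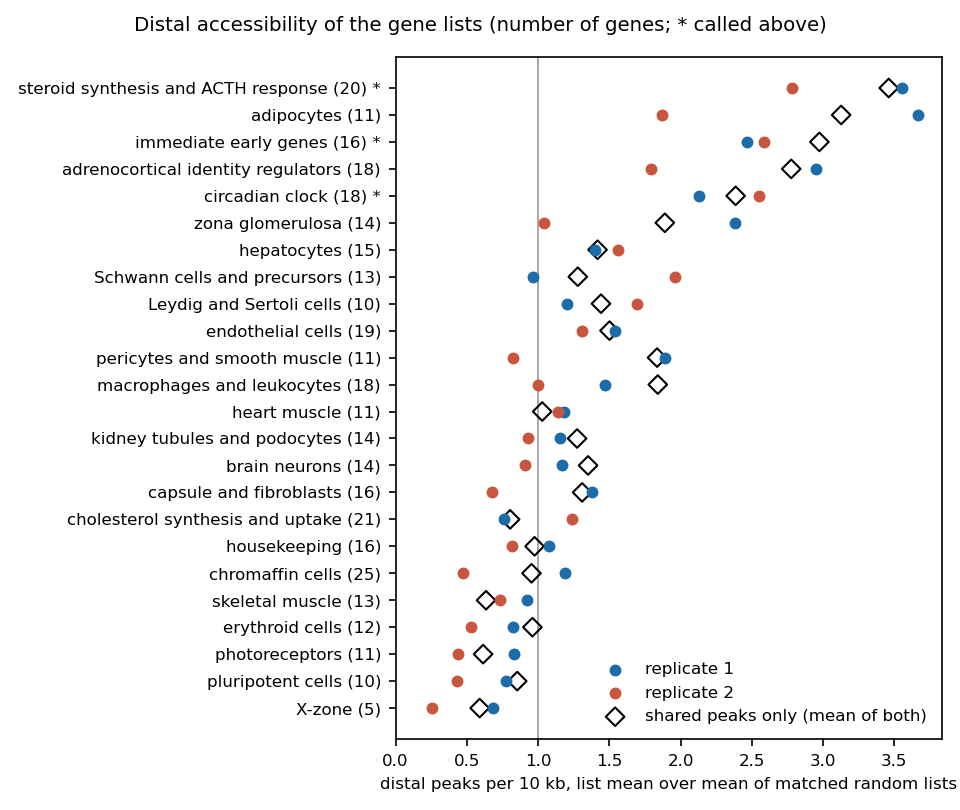
Distal peaks per 10 kb of each gene list divided by the mean of matched random lists (x axis, 1 means equal), with 1 point per library and an open diamond for shared peaks alone. Steroid genes lay at 3.17, immediate early genes at 2.53 and clock genes at 2.34 on average and were called above in both libraries, while the adipocyte and zona glomerulosa points of the 2 libraries lay far apart.

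The genes with the most distal peaks in both libraries were long annotated units. Gm20388, a unit spanning 119910841 to 124345722 on chromosome 8, had 495 and 710, and Fgfr2, a growth factor receptor annotated here from 130162451 to 133123350 on chromosome 7, had 187 and 192. Over spans of this length the counts cannot be assigned to the 2 genes themselves. Tns1 had 94 and 75, Camta1 71 and 128, Nav2 70 and 84, Zfhx3 91 and 63, Gse1 98 and 58, Ctif 53 and 109 and Wwox 52 and 84. By mean rank of height over both libraries, the highest shared peak lay on chromosome 17 at 39846781 to 39846900, inside CT010467.1 and 117 bp from the TSS of the long noncoding RNA Gm42418, with heights of 82.9 and 38.0. The next lay in Lars2, the mitochondrial leucine-tRNA ligase (chromosome 9, 123461921 to 123462100; 67.0 and 38.0), and in Mid1 (chromosome X, 169997981 to 169998420; 37.7 and 51.8). The remaining 2 were at promoters. The peak on chromosome 1 (88277521 to 88277760) lay 8 bp from the TSS of the centromere histone chaperone gene Hjurp. Its heights were 41.2 and 42.0. The peak on chromosome 17 (6430021 to 6430180) lay 11 bp from the TSS of Dynlt1b. Its heights were 40.1 and 48.3. Unique mapping of reads and copy number were not examined at any of these highest peaks. Their heights therefore need not mean unusually high accessibility.

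Footprints were enriched for the binding sequences of CTCF, NRF1, REST and NFI. Matches to the consensus of CTCF, the insulator protein, were denser in footprints than in the remaining peak bases by a log2 ratio of 6.25 ± 0.04 (SD, n = 2), which is 76.0-fold (40.6-fold against the 25 bp beside each footprint). The ratio was 6.18 ± 0.82 for NRF1, a regulator of housekeeping promoters, 6.01 ± 0.53 for REST, the repressor of neuronal genes, and 5.17 ± 0.34 for NFI. SP/KLF at 2.94 ± 0.04, ETS at 2.35 ± 0.28 and NFY at 0.90 ± 0.01 were also above all their letter shuffles in both libraries, which makes 7 of 24 consensus strings. The CRE string of CREB and ATF factors, the fifth highest at 3.29 ± 0.54, exceeded its shuffles in replicate 1 alone, but in both libraries when only footprints within peaks were counted (3.85 and 3.23). Low ratios were those of GATA at -1.22 and the steroid receptor element at -0.92, and neither lay below all shuffles. SP/KLF had 8 shuffles, so its comparison was coarser, and it was not called against the 25 bp beside each footprint. Its highest shuffle reached 2.81 and 2.84, close to its own 2.97 and 2.91. In distal peaks alone 3 strings were called, CTCF, NFI and REST.

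The NR5A1 consensus, the binding sequence of the steroidogenic nuclear receptor, reached a log2 ratio of 1.58 ± 0.49 (SD, n = 2) in footprints, which is 3.00-fold. It exceeded all 50 shuffles in replicate 1 (1.93 against at most 1.46), while 1 shuffle lay higher in replicate 2 (1.24 against 1.44), so it was not called. Its matches lay in 4908 footprint positions in replicate 1 and 1738 in replicate 2.

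**Figure D3:**
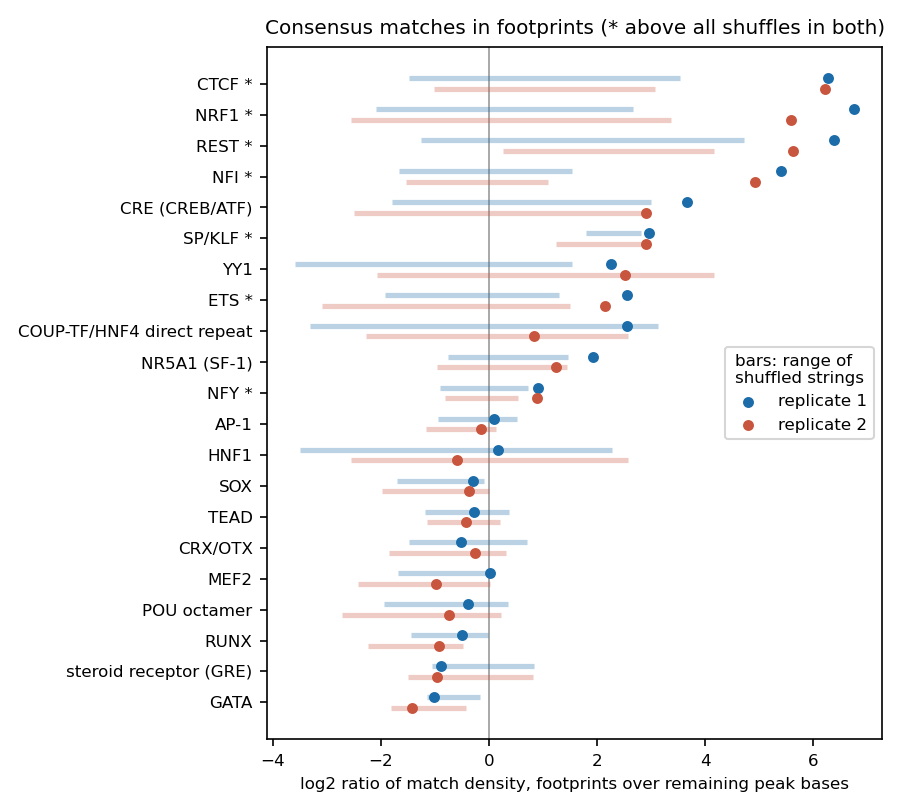
Log2 ratio of consensus density in footprints over the remaining peak bases for 21 of the 24 consensus strings, with 1 point per library and bars for the range of the letter-shuffled strings. CTCF, at 6.27 and 6.22, lies far right of its shuffles in both libraries, while NR5A1, at 1.93 and 1.24, exceeds all its shuffles in replicate 1 alone.

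Distal peaks held the sequences of NR5A1, AP-1, CTCF, NFI, MEF2 and REST more often than windows of the same GC content. The NR5A1 string was found in 6.52% and 4.67% of distal windows against 2.39% and 2.39% of the matched windows, a ratio of 2.34 ± 0.550 (SD, n = 2). AP-1, the site of FOS and JUN factors, was found in 10.7% and 6.80%, a ratio of 2.87 ± 0.933. CTCF had a ratio of 67.8 ± 2.34, NFI of 15.5 ± 12.7 (24.5 in replicate 1 and 6.52 in replicate 2) and MEF2, a muscle and neuron factor family, of 2.52 ± 1.14. Against windows 500 bp beside each peak, the ratio of CTCF was 24.6 and that of NFI 8.23. In the higher-ranked 50% of peaks the ratios were 171 and 21.1. The REST string lay in 215 and 159 distal windows against 0 and 1 matched windows, a difference carried by few comparison counts. GATA (1.12 ± 0.0638) and the E-box string (1.37 ± 0.145) were not called. The NR5A1 string lost its call in the higher-ranked 50% of peaks, where its ratio was 2.45 and a shuffle lay higher in replicate 1, and against windows 500 bp beside each peak, where it was 1.89. The MEF2 string was not called in the latter comparison either, with ratios of 1.37 and 0.920.

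Distal peaks at cortex genes held the NR5A1 string slightly more often than those at other genes, within the range of random lists. Over the 57 genes of 4 cortex lists, 59 of 676 distal peaks in replicate 1 (8.73%) and 44 of 754 in replicate 2 (5.84%) held it, against 6.65% and 4.68% elsewhere, a ratio of 1.28 ± 0.0457 (SD, n = 2; percentiles 88.17 and 78.8). Fgfr2, whose long span leaves the assignment uncertain, supplied 187 of the 676 and 192 of the 754 peaks. With the shorter string CAAGGTCA the ratio was 0.998. At chromaffin genes the E-box lay in 22.5% and 27.6% of distal peaks (ratio 1.46 ± 0.340; percentiles 80.9 and 99.4) and GATA in 12.7% and 12.1% (ratio 1.61 ± 0.0857), and neither was called.

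Within peaks shared by both libraries, 32 matches to the NR5A1 string, called sites here, lay at 16 of the 57 cortex genes. Of these, 20 and 17 lay in footprints. Over all peaks of replicate 1, 3647 matches lay in footprints and 3755 in the remaining peak bases. In replicate 2 the numbers were 1285 and 4417. Binding of NR5A1 itself was not measured. The long annotated span of Fgfr2 held 9 of the 32. Of these, 8 lay 226658 bp or more from any TSS of Fgfr2 itself, so their assignment to this gene is uncertain. Distances here are to TSS of the named gene, and closer TSS of other genes were not looked for. At Cyp11a1, TCAAGGTCA lay upstream of the gene on the reverse strand (chromosome 9, 58003500 to 58003508), 2907 bp from the nearest TSS of Cyp11a1. It lay in peaks of height 1.99 and 1.73. A second site, TCAAGGCCA, lay in an intron (58009145 to 58009153) in peaks of height 3.61 and 2.37. Both sites were in footprints in both libraries. At Scarb1, TCAAGGCCA lay 282 bp from an internal TSS (chromosome 5, 125286391 to 125286399) in peaks of height 2.24 and 1.71, and at Nr5a1 itself TCAAGGCCG lay outside the gene (chromosome 2, 38718871 to 38718879), 4333 bp from the TSS. Pde8b, a cAMP phosphodiesterase of the cortex, held CCAAGGCCG 18 bp from a TSS (chromosome 13, 95250350 to 95250358). The sites at Scarb1, Nr5a1 and Pde8b were in footprints in both libraries as well. The 5 sites were chosen after their values had been seen.

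Peaks with large heights were found in both libraries and low peaks were not. Of the peaks of replicate 1, 54.4% overlapped a peak of replicate 2, and 49.0% of the peaks of replicate 2 overlapped one of replicate 1, a mean of 51.7% ± 3.85 (SD, n = 2) against 2.21% and 1.97% for shuffled peaks. In the highest decile by height 99.8% and 99.6% were found, and in the lowest 8.44% and 0.205%. Shared regions numbered 67668, against 57050 and 70825 regions of a single library, and the Jaccard index of bases was 0.315. Across shared regions, which are not independent replicates, the heights had a Spearman correlation of 0.934. For the higher-ranked 50% of peaks the mean overlap was 82.2%. Footprints overlapped less evenly, with 30% of those of replicate 1 and 51.1% of those of replicate 2 found in the other library (40.5% ± 14.9, SD, n = 2), against 10.5% and 19.3% for random placement. Random placement was even over all peaks of the longer list, so part of this excess may only restate the sharing of peaks. A reciprocal overlap of at least 50% lowered the footprint value to 25.6%.

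**Figure D4:**
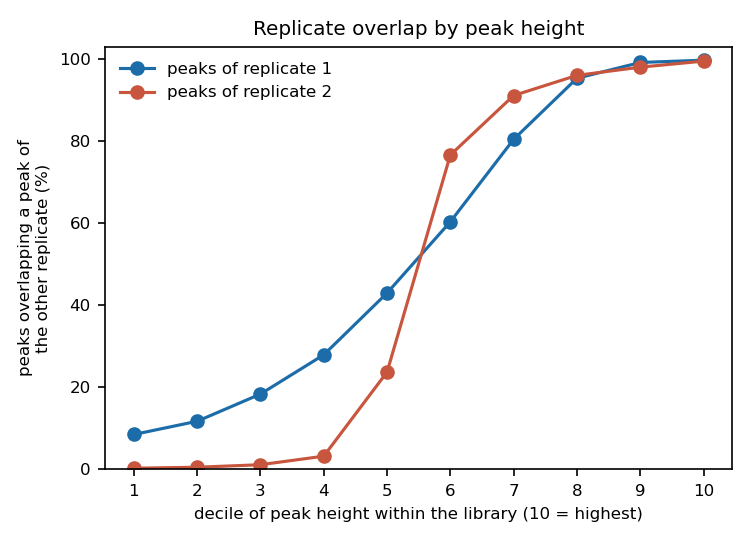
Percentage of peaks that overlapped a peak of the other library (y axis) by decile of peak height within the library (x axis, 10 is the highest), with 1 point per decile and library. The curves run from 8.44% to 99.8% for replicate 1 and from 0.205% to 99.6% for replicate 2.

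Promoters held more peaks than chance placement gave. Peaks within 1000 bp of a TSS made up 29.5% ± 1.86 (SD, n = 2) of each library, against 6.91% and 6.97% for shuffled peaks, while 34.8% ± 1.52 lay in introns, 28.6% ± 1.32 between genes and 7.15% ± 1.65 in other exons. Among shared peaks 40.8% lay at promoters, and in the longer deposited lists 23.7%.

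Peaks of a single library were lower, less GC-rich and less often at promoters than shared peaks. Peaks of replicate 2 without a partner numbered 72228 and had a median height of 0.205, against 1.43 for its shared peaks, and 37.7% of them held a footprint against 89.6%. The 57849 peaks of replicate 1 without a partner had a median height of 0.580 against 1.81, and 85.3% held a footprint. Of the replicate 2 group, 16.1% lay at promoters and 14% were mostly repeat sequence, against 18.8% and 4.86% in the replicate 1 group. Of the 229 distal peaks of replicate 2 alone at the 19 endothelial genes, most lay at 3 loci chosen after their values had been seen, Erg (104 distal peaks, 12 shared), Pecam1 (67, 5 shared) and Flt1 (60, 3 shared), and most other endothelial genes had no such excess. Distal peaks of replicate 1 alone held the CTCF string 13.9 times, AP-1 3.07 times and NR5A1 2.59 times as often as windows 500 bp beside them, and those of replicate 2 alone held them 0.809, 1.17 and 1.17 times as often. Against windows matched on GC content, a comparison added after the data were seen, the ratios were 35.9, 3.46 and 2.93 in replicate 1 and 2.08, 1.42 and 1.52 in replicate 2. With 1 library on each side no test was possible, and instrument, library and animals cannot be told apart.

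The X chromosome carried fewer peaks per Mb than every autosome in both libraries, and the Y chromosome almost none. X had 18.7 and 11.9 peaks per Mb, 0.280 ± 0.109 (SD, n = 2) of the autosomal median, while the autosomes ranged from 38.7 and 32.9 on chromosome 3 to 77.1 and 106.5 on chromosome 11. Y had 0.567 and 1.01 peaks per Mb, 0.0141 ± 0.00456 of the autosomal median (0.0381 in the longer lists). These densities were taken over the full chromosome length. Neither the share of Y to which reads can be placed uniquely nor the placement of CAST/EiJ reads was examined. The median height of promoter peaks on X was 0.579 of that of the autosomes in replicate 1 and 0.883 in replicate 2.

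**Figure D5:**
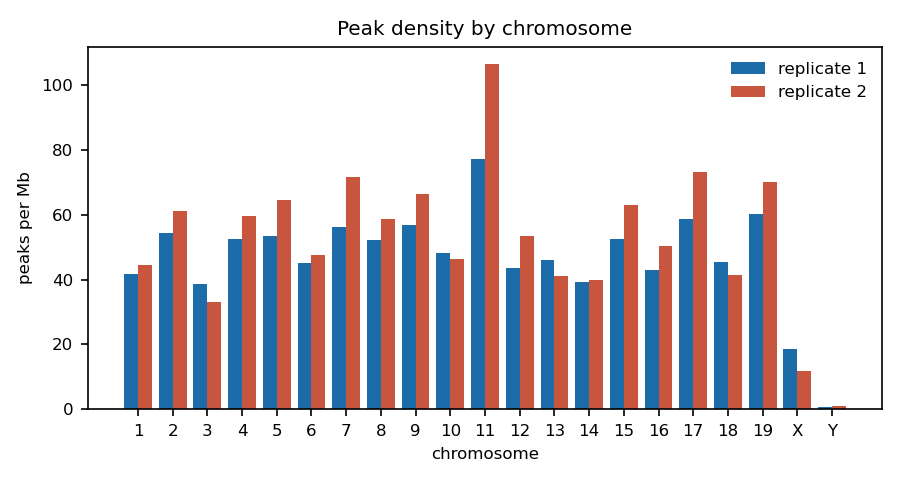
Peaks per Mb (y axis) on each chromosome (x axis), with 1 bar per library. The bars of X reach 18.7 and 11.9 and those of chromosome 11 reach 77.1 and 106.5.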

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

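The count of neighbouring peaks, the heights of shared peaks on X and the comparison of replicate 2 peaks with matched windows were chosen only after the results had been seen.

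The per-base FDR values outside the listed peaks were not analysed in the report. Outside all peaks of the longer lists, 84720 runs of bases with an FDR under 0.05 were listed in replicate 1 (23.8 Mb) and 99951 in replicate 2 (26.8 Mb), with no control sample to set them against.

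Of the peaks of replicate 2, 63706 (45.0%) had no base under an FDR of 0.05 in replicate 1, against 26121 (20.6%) in the other direction. GC bias in library 2 remains open. Bias predicted a GC content above that of shared peaks. The 72228 peaks called in replicate 2 alone had a median of 52.5%, below the 56.7% of its shared peaks. Peaks of replicate 1 alone were also below its shared peaks (51.6% against 56.1%), so this comparison cannot decide. Windows 500 bp beside the distal peaks of replicate 2 alone held 47.8% GC, against 46.6% beside its shared ones. Weak calls near the threshold remain open, since 7.55% of the peaks of replicate 2 alone were in the higher-ranked 50% of the library. Of that higher-ranked 50%, 92.3% were found in replicate 1. The weak calls may be piled up in limited stretches of the chromosomes, since 69.0% had at least 20 peaks of the library within 25 kb, against 2.75% of the peaks of replicate 1 alone, and the same stretches, 1409 blocks over 133.5 Mb, held 48.1% of all its peaks and 151.8 peaks of replicate 1 per Mb against 46.6 over all chromosomes, and what makes such stretches was not tested. Regulatory sites used only in the animals of replicate 2 also remain open, since 4 consensus strings were found in these peaks at a median of 0.988 times the share in their own flanks (2.47 times in shared peaks) but 1.47 times (1.05 to 2.08) that in windows matched on GC content, and flanks can overlap other peaks.

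The X chromosome carried 0.280 of the autosomal median of peaks per Mb. A lower number of genes on X is argued against as the whole cause, since X had 3.37 and 2.15 peaks per protein-coding gene, below the lowest autosomes at 4.04 and 5.14. The single copy of X in males remains open. The promoter peaks of X had 0.579 of the autosomal height in replicate 1 and 0.883 in replicate 2. The distal peaks had 0.605 and 1.90. The value of 1.90 depended on which peaks were taken. In replicate 2 the distal ratio was 1.41 with equal numbers of peaks, 0.609 in the longer list and 0.792 among the higher-ranked peaks. The promoter ratios of replicate 2 were 0.838, 0.709 and 0.759 in the same order. Distal heights of replicate 2 were therefore lower on X in some of these settings and not in others. Among shared promoter peaks the ratios were 0.585 and 0.578, and among shared distal peaks 0.653 and 0.641. Lower heights of this kind would be seen with a single copy, but the hypothesis was found and tested on the same data.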

How the results depend on the processing

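Among the alternatives in this part, the restriction to shared peaks and the longer lists for X and Y were chosen after the data had been seen. No called mean over both libraries changed direction, but the MEF2 string, called in distal peaks, fell to 0.920 in replicate 2 against windows beside the peak (1.37 in replicate 1). Values that were not called changed direction, as for chromaffin distal density (0.473 and 1.19 in the single libraries), cholesterol distal density (1.24 and 0.760) and GATA in distal peaks (1.12, and 0.754 against windows beside the peak). Mean peak overlap (51.7%) was 44.5% with reciprocal overlap of at least 50% and 82.2% in the higher-ranked 50% of peaks, and footprint overlap (40.5%) was 25.6% with reciprocal overlap. The promoter share of peaks (29.5%) was 23.5% within 500 bp, 39.7% within 2500 bp, 23.7% in the longer lists and 40.8% among shared peaks, with 28.1% and 30.8% in the single libraries. The density of X over the autosomal median was 0.203 to 0.358 in the single libraries and that of Y 0.0109 to 0.0173. In the longer lists X had 0.390 and Y 0.0381, and in the higher-ranked 50% of peaks Y had 0.00638. Lists called for promoters (4) were 1 within 2500 bp and 8 with shared peaks, and lists called for distal density (3) were 5 in the higher-ranked 50% and 5 with shared peaks, each time with the main 3 kept. Each library on its own gave 3 to 6 lists for distal density, the 6 coming from replicate 1. For promoter shares each library gave 4 to 6 lists. Against unmatched lists 6 were called for promoters, with 0 of the main 4 among them. The steroid list had a promoter ratio of 1.32 against unmatched lists and was not called, while each library on its own gave 1.46 to 1.56 for its promoters and 2.78 to 3.56 for its distal density. Of the footprint strings (7), 3 were called in distal peaks alone, and each library on its own gave 7 to 11, with 11 in replicate 1. The NR5A1 string ranged from 1.24 (replicate 2, not called) to 1.93 (replicate 1, called) in footprints, and in distal peaks it was not called at 2.45 in the higher-ranked 50% and at 1.89 against windows beside the peak, with 1.95 to 2.73 in the single libraries, which each called 6 strings in distal peaks. At cortex genes the NR5A1 ratio (1.28) was 1.25 to 1.31 in the single libraries, 1.61 in the higher-ranked 50%, 1.38 with shared peaks and 0.998 with the shorter string, and was called in none of these. For these changes, apart from stricter or wider definitions, the cause was not tested. Of the values of single lists and strings, 562 stayed on their side of the threshold, 31 passed it and 14 lost it. The 562 include values that were called in neither setting. A call needed both libraries, so taking a single library could not lose it. These counts therefore do not measure how well the calls held. The steroid list and the NR5A1 string, which lost calls as given above, are not in these counts. Peak and footprint overlap need both libraries, so no value without a replicate exists. No paired analysis was possible because there was 1 group. The depth is unknown, replicate 2 had fewer footprints, and a doubling of distal density was found in 26% of simulated lists, so missing calls are weak evidence.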

Other observations

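The genes named in this part were chosen after their values had been seen, and no test was added for them.

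Genes of brown and white fat cells were accessible in the gland preparations. All 11 adipocyte promoters carried a peak in replicate 1 and 9 in replicate 2. Ucp1, the uncoupling protein of brown fat, had promoter heights of 2.51 and 1.76 and 9 and 2 distal peaks. Cidea, which coats lipid droplets in brown fat, had heights of 4.01 and 3.44 and 5 distal peaks in each library, all 5 shared. Prdm16, a regulator of brown fat identity, had 31 and 11 distal peaks, of which 9 were shared. Pparg, the nuclear receptor of fat cell differentiation, had 12 and 7, and Adipoq, a secreted fat hormone, had a promoter peak in replicate 1 alone (1.34).

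Chgb, which encodes chromogranin B, had heights of 10.6 and 9.03 and Scg2, secretogranin II, had 6.12 and 4.42, and neither had a distal peak. In the steroid list, Por, the electron donor of microsomal steroid hydroxylases, had heights of 14.5 and 16.3 and Fdxr, the donor in mitochondria, 12.5 and 14.1. Cyp17a1, a steroid hydroxylase of the testis, had promoter heights of 2.00 and 1.83, while Insl3 and Fshr, hormone and receptor genes of Leydig and Sertoli cells, had no promoter peak. Wt1, a regulator of the adrenal and gonadal primordium, had 0.935 and 0.940.

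At 3 of the 19 endothelial genes, replicate 2 had many more distal peaks than replicate 1, while most others had no such excess. Erg had 14 distal peaks in replicate 1 and 104 in replicate 2, with 12 shared, Flt1 had 11 and 60, with 3 shared, and Pecam1 had 7 and 67, with 5 shared.

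Promoter accessibility followed CpG content. The accessible share was 25.5% and 21.9% among the 7121 genes with the fewest promoter CpGs, 84.1% and 79.9% among the 7434 in the middle bin and 98.5% and 97.1% among the 7356 with the most. Outside the dense blocks of replicate 2, 75% of its peaks were found in replicate 1, and its median peak height was 0.234 inside the blocks and 1.05 outside them.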
